A study of Mus musculus with 6 samples.

How the data were processed

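MicroRNA levels were measured in 6 mouse lung samples, 2 from CC10-rtTA-IL13 transgenic mice (TG) and 4 from wildtype mice (WT), with 1 array per sample. Per the labels' protocols, total RNA was extracted with TRIzol and biotin-labelled by the Affymetrix procedure. The labels call the samples biological replicates. The deposited table holds 1 value per probe set and array. The authors' deposited values were taken as log2, since they run from 3.37 to 13.36 with a dense floor near 4, and the highest exceed what the natural logarithm of a 16-bit scanner's range allows. The base is thus inferred, and all fold changes rest on it. Array medians lay between 4.02 and 4.03, near the plant medians of 3.97 to 4.00, which shows a similar background level; whether the signals had been scaled between arrays is unknown. The background correction, summarization and normalization are not given in the sources used here, nor is the miRBase version behind the probe sets. No scan date or batch was given, so none could be tested, and no column was left unused (0 columns).

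Probe sets were classed by the species prefix of their names into 609 mouse, 4262 other animal, 1631 plant, 201 viral and 922 small nucleolar RNA probe sets. A probe set counted as detected on an array when above the 95th percentile of that array's plant probe sets, which lay between 4.22 and 4.33, and was tested when detected on 2 or more arrays. This left 197 mouse probe sets and left out 412. Gene names were looked up in a RefSeq table of assembly GRCm38.p6, used only for names and neighbours, which named 191 of the 197. The 6 without a match were miR-685, miR-699, miR-805, miR-720, miR-197 and miR-1196. No coordinates are printed because the deposited table names no genome build.

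TG was compared with WT on all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, not robust), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. Where a mouse probe set was undetected on every array of 1 group, and so was every other mammal's probe set of its name, the fold was computed against the higher of the detection limit and the measured value on each array and is given as a lower bound, or not at all where it is under 1. Where only some arrays of a group detected a probe set given with a fold, or only another mammal's probe set was detected there, the fold with each value under the limit of its array set to that limit stands beside the measured one. The 21 miRNA lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry where 3 or more members were tested, which held for 13 lists, with adjustment over the lists. Single values were tested by exact permutation over the 15 splits of the arrays. Simulated data for this comparison had 197 probe sets, of which 40 were changed in each of 50 simulations. On the log2 scale 5% of changes of 0.5 were recovered, 40.2% of changes of 1, 87.4% of changes of 2 and 99% of changes of 3. Of the calls, 4.39% were false. The simulated noise was independent between probe sets. These shares therefore do not hold where an array shifts many probe sets together.

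The lists, the tests, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took the called probe sets whose 2 TG arrays lay on 1 side of all WT arrays (up to 10 per direction), every tested member of a core panel of 16 miRNAs, and up to 4 members with the smallest p in each list. After the values had been seen, 1 to 4 members per list were compared by how many names and sign changes each would bring into the text, the number was set to 2 for every list to shorten it, and let-7c was added; 49 miRNAs are named under this rule. Alternatives were no detection filter, the 99th plant percentile, detection on 4 or more arrays, quantile normalization, centring on the tested or the plant median, a mean-variance trend, robust eBayes, array weights, all animal probe sets in 1 test, a fold change of at least 1.5, leaving out each array in turn, and the replicate number as a block. Alternatives chosen after the data had been seen were only WT replicates 2 and 3, only WT replicates 1 and 4 (each with the filter recomputed on the arrays used and with the filter of all 6 arrays), the fit without a block on the arrays numbered 1 and 2, averaging of same-name mammalian probe sets, and the number of detected other-animal probe sets as a covariate. The last includes probe sets that share names with tested mouse miRNAs. Exploratory fits of the main design preceded the final ones and gave the same count.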

Results

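MicroRNA levels were measured in the left upper lung lobe of 6 mice on arrays carrying probe sets for miRNAs of many species. In the 2 transgenic mice (TG) a doxycycline-responsive transactivator under the CC10 promoter, which is active in club cells of the airway, drives interleukin 13, a cytokine of type 2 inflammation. The other 4 mice were wildtype (WT). All 6 were C57BL/6 mice of 6 to 10 weeks that had drunk water with 2 mg/mL doxycycline for 7 days, so the drug itself did not differ between the groups. The comparison of TG with WT asks which lung miRNAs differ between mice with this induced transgene and wildtype mice. No group carried the transactivator alone, so its presence in TG cannot be told apart from the induced interleukin 13. The table held 7625 probe sets, of which 609 were for mouse miRNAs, and 197 of these were detected on at least 2 arrays and tested. The number of arrays limits the precision of every value. The arrays measure no interleukin 13, so the genotype labels could not be checked from the data.

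The 6 arrays had a similar background level and differed in how many mouse miRNAs they detected. Their detection limits were 4.22 and 4.25 in TG and 4.30, 4.27, 4.28 and 4.33 for WT replicates 1 to 4. The limit was thus lower on both TG arrays, and how far this moved the counts was not tested. The TG arrays detected 201 and 199 mouse probe sets, and the WT arrays 149, 172, 146 and 132 for replicates 1 to 4. The means were 200.0 ± 1.41 (SD, n = 2) and 149.75 ± 16.6 (SD, n = 4). The exact two-sided permutation test gave p = 0.0667, the smallest p that 15 splits of 6 arrays allow, so no test of this kind could reach 0.05 here. Over the 197 tested probe sets the median log2 difference (TG minus WT) was 0.21, with 130 differences above 0 and 67 below. It was -0.23 when each array was centred on the median of its tested probe sets, a shift of 0.44 that turns 66 positive differences negative, so small positive differences have no settled direction and are given as values. The TG arrays correlated at r = 0.983 across probe sets, and WT pairs at 0.885 to 0.961. WT replicate 2 correlated at 0.963 with each TG array, above its values of 0.949, 0.961 and 0.885 with WT replicates 1, 3 and 4. It also lay nearest the TG arrays on the first principal component, at 3.27 beside 5.23 and 5.51, with the other WT arrays at -1.78 to -8.55. WT replicates 1 and 4 had highest values of 11.50 and 11.42, against 13.13 to 13.36 on the other arrays.

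In TG, 6 miRNAs were higher than in WT past the threshold, and none was lower. miR-127, detected on 1 of 4 WT arrays, rose 4.18-fold (4.04-fold with values under the detection limit of their array set to it), with log2 values of 6.56 ± 0.50 in TG (SD, n = 2) and 4.50 ± 0.52 in WT (SD, n = 4). miR-685, detected on 3 of 4 WT arrays, rose 4.07-fold (3.98-fold with the limit), from 4.59 ± 0.35 to 6.61 ± 0.58. Its name had no match in the RefSeq table, so no miRNA gene was identified for it. The same holds for miR-720 and miR-805, counted below among names ascribed to fragments of longer RNAs. miR-34a, a direct transcriptional target of p53, rose 2.95-fold, from 4.89 ± 0.42 to 6.45 ± 0.15. miR-146b, which is induced by inflammatory signalling and targets adaptors of Toll-like receptor signalling, was detected on 1 of 4 WT arrays and rose 2.84-fold as measured, from 4.19 ± 0.38 to 5.70 ± 0.08, and 2.46-fold with the limit, as the measured WT mean lies in the background. The same holds for miR-362-5p, detected on 1 of 4 WT arrays, which rose 2.09-fold as measured, from 4.19 ± 0.10 to 5.26 ± 0.04, and 1.94-fold with the limit. The mouse probe set of miR-379 was detected on 0 of 4 WT arrays and rose 2.28-fold as measured, from 4.07 ± 0.13 to 5.25 ± 0.39, and 1.94-fold with the limit; 2 of its 4 probe sets of other mammals were detected in WT. The log2 differences of the 6 were 2.06 ± 0.38 (SE), 2.02 ± 0.33, 1.56 ± 0.31, 1.51 ± 0.29, 1.07 ± 0.21 and 1.19 ± 0.25 in this order. limma with Benjamini-Hochberg adjustment gave adjusted p = 0.0428 for the first 5 and 0.0478 for miR-379. In all 6, both TG arrays lay above all 4 WT arrays.

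**Figure D1:**
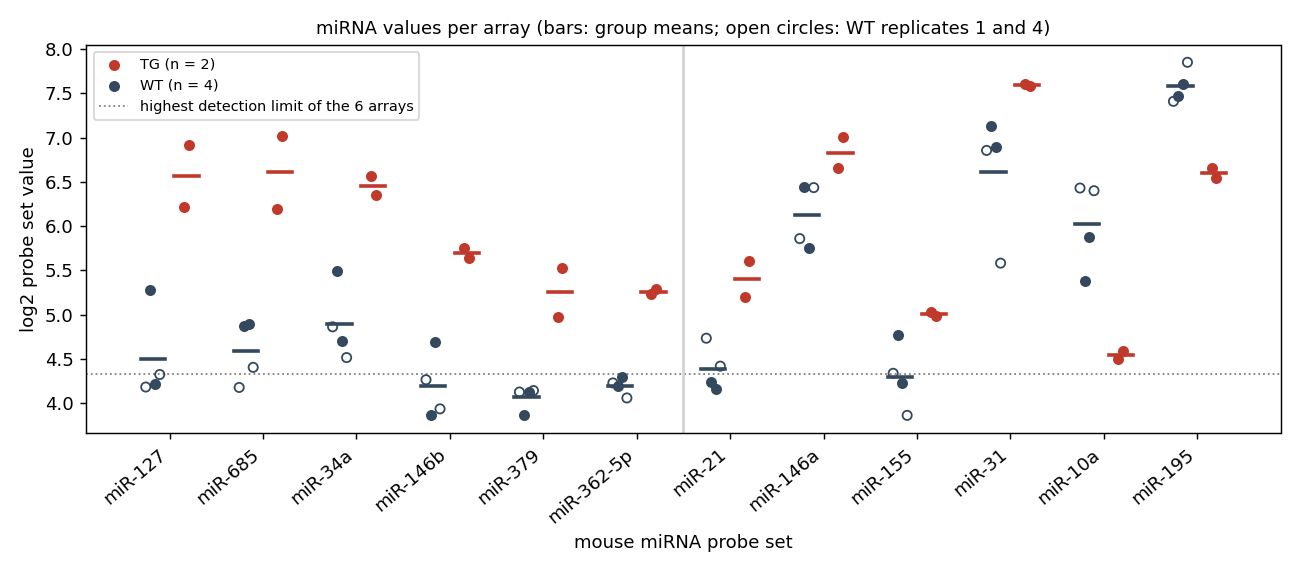
Log2 probe set values (vertical axis) of 12 mouse miRNAs (horizontal axis) on each of the 2 TG and 4 WT arrays, with bars at the group means, open circles for WT replicates 1 and 4 and a dotted line at the highest detection limit of the arrays. The 6 miRNAs left of the vertical line passed the threshold with both TG arrays above all WT arrays, and those to its right did not pass it.

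At an unadjusted p under 0.05 there were 39 probe sets, 34 higher and 5 lower in TG. Both TG arrays lay above all WT arrays for 58 of the 197 probe sets and below all for 13. For any given probe set chance gives 6.67% on each side. The probe sets share the same arrays and can shift together, so this rate cannot judge the counts of 58 and 13. Such counts were not computed for the other splits of the arrays. The count of calls changed with single arrays. Leaving out TG replicate 1, TG replicate 2, WT replicate 1 or WT replicate 3 left 0 calls, leaving out WT replicate 4 left 4 and leaving out WT replicate 2 gave 27. Quantile normalization gave 0 calls, centring on the tested median 2, testing without the detection filter 1, the detection count as a covariate 0 and array weights 33.

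The array also carries probe sets for the same miRNA names in other mammals. Without probe sequences it is not known which of them bind the mouse RNA; of 897 sharing a name with a tested miRNA, 59 differed from the mouse probe set by over 1 log2 unit in mean level, 1 of them among the 33 of the called names. For miR-127, all 11 detected probe sets of other mammals were higher in TG, by 1.82 to 2.78 on the log2 scale. All 14 for miR-34a were higher, by 0.81 to 1.75. The 2 for miR-146b differed by 1.09 and 2.39, the 4 for miR-379 by 0.73 to 1.10, and the 2 for miR-362-5p by 0.68 and 0.85. miR-685 had no such probe set. They come from the same 6 RNA samples and add no animals.

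**Figure D2:**
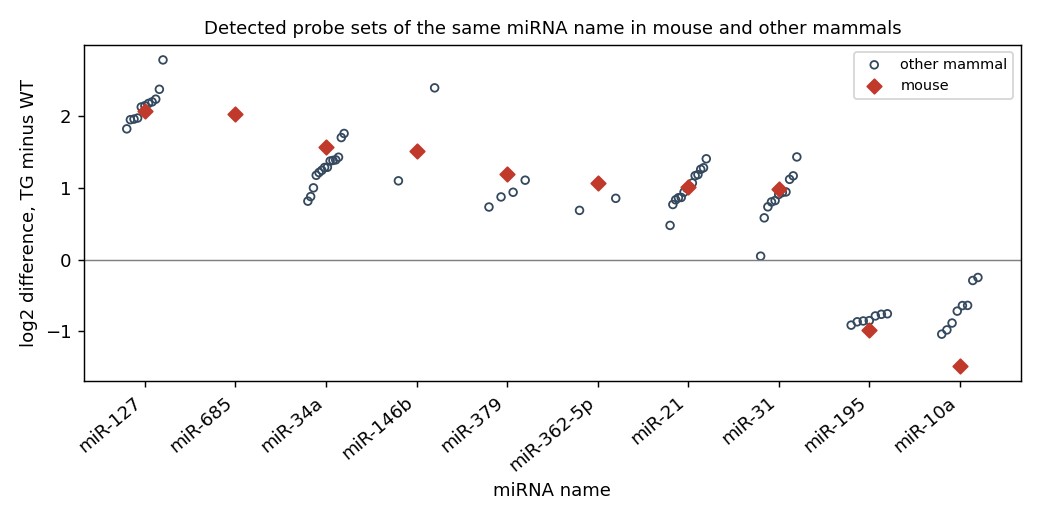
Log2 difference, TG minus WT (vertical axis), of the detected probe sets of 10 miRNA names (horizontal axis), with diamonds for the mouse probe set and open circles for other mammals. For miR-127 the other mammals' probe sets lie from 1.82 to 2.78 around the mouse value of 2.06, and miR-685 has the mouse probe set alone.

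miR-21, often described as raised in allergic airway inflammation, had a log2 value of 5.40 ± 0.29 in TG (SD, n = 2) and 4.39 ± 0.25 in WT (SD, n = 4). It was detected on 2 of 4 WT arrays. The difference was 1.01 ± 0.26 (SE), 2.02-fold (1.97-fold with the limit), with an adjusted p of 0.0812 by limma, which did not pass the threshold. Both TG arrays lay above all WT arrays, and the exact two-sided permutation test gave p = 0.0667, the smallest possible. All 14 probe sets of other mammals for miR-21 were higher in TG, by 0.47 to 1.40. Adjusted p was 0.0225 with same-name probe sets averaged and 0.0146 with array weights. With only WT replicates 2 and 3 it was 0.0483, or 0.0837 when the filter of all 6 arrays was kept. Over the 24 alternatives it ran from 0.0146 to 0.696, and 3 passed.

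miRNAs known to respond to inflammation were higher in TG as a group. All 8 tested members had positive differences, with a mean of 0.85, and camera gave an adjusted p of 0.0140 over the 13 lists with at least 3 tested members. With an estimated correlation the adjusted p = 0.319, and fry gave an adjusted p of 0.0165. With the preset correlation the list passed in 21 of 22 alternatives, which reuse the same arrays. One member passed over all probe sets tested, miR-146b, and 2 when adjusted over the list alone, miR-146b and miR-21. miR-31, at 0.98 ± 0.43 (SE), miR-155, which takes part in immune cell activation, at 0.71 ± 0.29, and miR-146a, at 0.71 ± 0.29, did not pass. Over the 24 alternatives miR-31 ran from 0.11 to 1.37, miR-155 from 0.15 to 0.91 and miR-146a from 0.27 to 0.88. Averaging same-name probe sets brought miR-155 to 0.21 and miR-146a to 0.44. Of other mammals' probe sets, all 4 for miR-146a were detected but 0 of the 3 for miR-155. The miR-155 average thus mixes the mouse value with background. The other 3 tested members did not pass either, and miR-147 and miR-212 were not tested. With the number of detected other-animal probe sets of each array as a covariate, the list's mean was 0.50 with a camera adjusted p of 0.0562.

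The 5 members of the miR-30 family, abundant in lung, were lower in TG as a group relative to the other tested miRNAs, with a mean difference of -0.39 and a camera adjusted p of 0.0151. The adjusted p = 0.319 with an estimated correlation, and fry, which tests for a common direction, gave an adjusted p of 0.484. No member passed alone, miR-30a being at -0.74 ± 0.35 (SE) and miR-30c at -0.50 ± 0.25. The call ended without WT replicate 4, where the mean was -0.23 and the adjusted p 0.0643, and with only WT replicates 2 and 3, where they were -0.25 and 0.0933. On the arrays numbered 1 and 2 it was -0.087, with an adjusted p of 0.467 with the replicate block and 0.409 without it. The call also ended with centring on the tested median, without the detection filter and with the detection count as a covariate. The camera adjusted p was 0.117, 0.0516 and 0.958 there. With that centring, which shifts every difference down, the mean was -0.82.

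miR-127 and miR-379 belong to the imprinted Dlk1-Dio3 cluster, which holds many miRNA genes expressed from the maternal chromosome. Of the 61 mouse probe sets for its members, 8 were tested, and 7 of these had positive differences with a mean of 0.71. Of these, 2 passed over all probe sets and 3 when adjusted over the list alone, the third being miR-134, whose mouse probe set was detected on 0 WT arrays, with a measured difference of 0.80 ± 0.23 (SE). miR-134 lies outside the naming rule and is named after its value was seen. The camera adjusted p was 0.0693, or 0.319 with an estimated correlation, and that of fry was 0.0165. Without WT replicate 4 the camera adjusted p was 0.0288, and the list passed in 7 of 22 alternatives, with adjusted p from 0.00130 to 0.903.

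**Figure D3:**
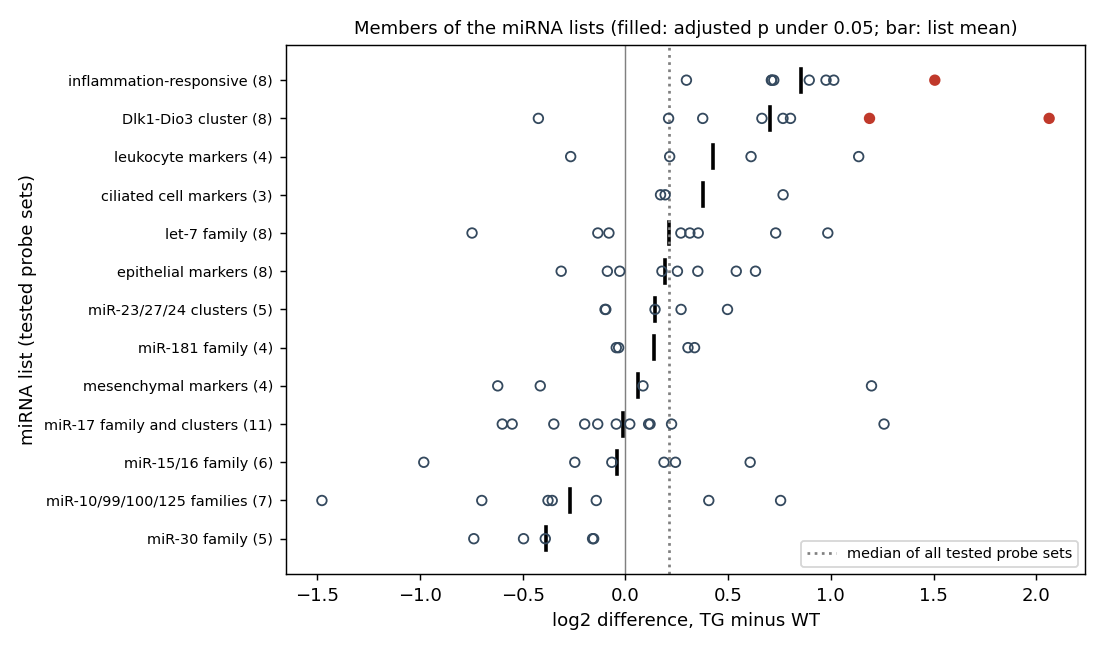
Log2 difference, TG minus WT (horizontal axis), of each tested member of the 13 lists with at least 3 tested members (vertical axis, number tested in brackets). Filled points passed the threshold, bars are list means and the dotted line is the median of all tested probe sets, 0.21; the inflammation-responsive list has the highest mean, 0.85, and the miR-30 family the lowest, -0.39, and 7 list means from 0.06 to 0.42 fall below 0 when arrays are centred on the tested median.

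Markers of leukocytes had 4 tested members, 3 with positive differences, a mean of 0.42, a camera adjusted p of 0.792 and a fry adjusted p of 0.190. miR-342-3p, expressed in lymphocytes, had a difference of 1.14 ± 0.29 (SE) that passed when adjusted over the list alone but not over all probe sets. There it passed in 4 of 24 alternatives (array weights, without WT replicate 2 at an adjusted p of 0.0189, and only WT replicates 1 and 4 under both filters). Over these 24 its difference ran from 0.41 to 1.42. miR-342-5p was at 0.61 ± 0.30. The mouse probe set of miR-223, a marker of myeloid cells, was detected on 0 of 2 TG arrays and 2 of 4 WT arrays, with a measured difference of -0.27 ± 0.25; only 1 of 3 detected probe sets of other mammals had the same sign, and they ran from -0.12 to 0.17. miR-142-3p and miR-142-5p, found across blood cells, were detected on 0 arrays and were not tested. Of the erythroid markers, miR-451 differed by -0.01 ± 0.29 and miR-486 by 0.31 ± 0.57, and neither of the 2 tested passed.

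Among markers of airway and structural cells no member passed over all probe sets tested. The 8 epithelial markers had a mean of 0.19 (camera adjusted p = 0.945), with miR-200c at 0.54 ± 0.24 (SE) and miR-375 at 0.25 ± 0.35. The 3 ciliated cell markers had a mean of 0.38 (camera adjusted p = 0.804), with miR-34c at 0.17 ± 0.35. The mouse probe sets of miR-205, a basal cell miRNA, and of the ciliated cell miRNA miR-449a were detected on 0 WT arrays. Their measured differences of 0.63 ± 0.22 and 0.77 ± 0.29 did not pass. For miR-449a no other mammal's probe set was detected in WT either. Against the WT detection limits, the mean of its 2 TG arrays gave a lower bound of 1.40-fold. That bound rests on TG replicate 1 at 5.24, as TG replicate 2 at 4.33 lay at the level of the WT limits, 4.27 to 4.33. The sole tested endothelial marker, miR-126-3p, was at -1.05 ± 0.44 and passed in its list of 1 but not over all probe sets. There it passed with array weights and without WT replicate 2 (adjusted p of 0.0324 and 0.0328). Over 24 alternatives its difference ran from -1.49 to -0.21. Of the smooth muscle markers, miR-145 was at 0.58 ± 0.35 and miR-143 at -0.50 ± 0.38. The 4 mesenchymal markers had a mean of 0.06 and a median of -0.16 (camera adjusted p = 0.792, direction down), with miR-199a-5p at 1.20 ± 0.31, past the threshold in the list alone, and miR-199b at -0.62 ± 0.38. Of 7 striated muscle markers only miR-133b was tested, its mouse probe set detected on 0 TG arrays with a measured difference of -0.27 ± 0.24 and its 1 detected probe set of another mammal at 0.11, and miR-1 was detected on 1 array. Of 6 markers of brain, liver and pancreas only miR-122 was tested, at 0.35 ± 0.25.

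The remaining lists are families and clusters of related sequence or position, and none passed with all 6 arrays and the filter above. miR-10a, encoded within a Hox gene cluster, had log2 values of 4.55 ± 0.06 in TG (SD, n = 2) and 6.02 ± 0.50 in WT (SD, n = 4), with a difference of -1.48 ± 0.34 (SE) and an adjusted p of 0.0604 by limma. It passed in its list alone (the miR-10, miR-99, miR-100 and miR-125 families, 7 tested, mean -0.27, camera adjusted p = 0.0613), where miR-99b was at 0.76 ± 0.31. That list passed in 8 of 22 alternatives, with adjusted p from 0.0247 to 0.958, among them 0.0247 without TG replicate 2, 0.0303 without WT replicate 2 and 0.0288 without WT replicate 4. miR-195 was at -0.98 ± 0.23 with an adjusted p of 0.0656 and passed in the miR-15/16 family alone (6 tested, mean -0.04, median 0.06, camera adjusted p = 0.190), where miR-15b was at 0.61 ± 0.38, with 8 of 13 detected probe sets of other mammals of its sign and 0.22 after averaging. Without WT replicate 2 the adjusted p was 0.0323 for miR-195 and 0.0131 for miR-10a, and averaging brought miR-10a to -0.71. Over 24 alternatives the difference ran from -1.91 to -0.39 for miR-10a and from -1.42 to -0.84 for miR-195. The 8 tested let-7 members had a mean of 0.21 but a camera direction of down (adjusted p = 0.792), with let-7f at -0.75 ± 0.31, let-7b at 0.99 ± 0.58 and let-7a at -0.13 ± 0.22. The let-7b difference was 0.10 with only WT replicates 2 and 3, 1.87 and past the threshold with only WT replicates 1 and 4, and 0.000996 with quantile normalization. The miR-17 family and clusters had 11 tested members and a mean of -0.01 (camera adjusted p = 0.160). In these, miR-92b was at 1.26 ± 0.42 and miR-106b at -0.60 ± 0.27. miR-92b passed the threshold without WT replicate 2 (adjusted p of 0.0189) and in 4 of 24 alternatives in all. Over these 24 its difference ran from 0.018 to 1.73. Only 7 of 12 detected probe sets of other mammals for miR-106b had its sign, and averaging brought it to -0.045. The miR-181 family (4 tested, mean 0.14, camera adjusted p = 0.804) held miR-181c at 0.34 ± 0.23 and miR-181b at 0.30 ± 0.63. The miR-23/27/24 clusters (5 tested, mean 0.14, camera adjusted p = 0.817) held miR-23b at 0.50 ± 0.29 and miR-24 at 0.27 ± 0.29. In both of these, and in the epithelial list, the camera direction was down while the mean was above 0, since camera compares a list with the other tested probe sets. Lists with 2 tested members had no set test. In the miR-29 family miR-29c was at 0.21 ± 0.23 and miR-29a at -0.17 ± 0.38, in the miR-183 cluster miR-182 at 0.57 ± 0.25 and miR-183 at 0.07 ± 0.31, and in the Sfmbt2 cluster miR-467f at 0.18 ± 0.21 (undetected in WT, with a TG mean too near the detection limit for a fold) and miR-669c at 0.07 ± 0.24.

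Small nucleolar RNAs, which guide modification of ribosomal RNA, were measured with 922 probe sets designed on human sequence, of which 22 were detected and tested. In TG, 2 were higher and none lower, with 7 at an unadjusted p under 0.05. Both are named because the count was small. The probe set ENSG00000199411_s_st, detected on 3 of 4 WT arrays, was 1.68-fold higher (1.67-fold with the limit), with a difference of 0.75 ± 0.16 (SE) and an adjusted p of 0.0203 by limma. U23 had a measured difference of 0.52 ± 0.13 and an adjusted p of 0.0253; it was undetected on all WT arrays and was at least 1.11-fold higher in TG. The count was 0 without TG replicate 1 or WT replicate 4, and 0 with quantile normalization or centring on the tested median.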

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

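Every test of an explanation in this part was chosen only after the result was seen, while the rules that picked the single arrays and outside probe sets were fixed before the data were examined; how many WT sets were checked follows the named miRNAs, whose number per list was set later.

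Of 53 sets of 4 WT values checked, 5 held an array far from the others, where chance gives about 1 in 20. WT replicate 2 lay apart for miR-127, at a log2 value of 5.28 against 4.18 to 4.32 on the other WT arrays, and for miR-379, at 3.87 against 4.12 to 4.14. It also lay apart for miR-183, at 4.67 against 3.903 to 4.002, and for miR-122, at 4.35 against 3.90 to 3.96. All 4 WT values of miR-379 lay under the WT detection limits of 4.27 to 4.33, so that flag concerns background values. For miR-127, miR-183 and miR-122 WT replicate 2 was the only WT array above its detection limit, which was 4.27. WT replicate 4 lay apart for miR-182, at 5.17 against 5.60 to 5.63.

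Outside the mouse names, 387 detected probe sets of other animals and viruses carried names without a mouse probe set, and limma called 8 of them, all higher in TG; none of the 24 viral ones was called. In all 8, both TG arrays lay above all WT arrays. Several carry another form of a name given above: hsa-miR-127-3p differed by 2.31, hsa-miR-146b-5p by 1.18 and mml-miR-146b-5p by 1.38 on the log2 scale. bta-miR-532 differed by 1.76, hsa-miR-502-3p by 1.22 and cfa-miR-502 by 1.15. The largest difference was that of hsa-miR-1826, at 3.38, and hsa-miR-923 differed by 1.01.

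The 6 called miRNAs were all higher in TG, and the TG arrays, whose detection limits were lower, also detected more probe sets. A probe set that fails alone is argued against for 5 of the 6, since 33 of 33 detected other-mammal probe sets of their names were higher in TG; miR-685 had 0 such probe sets, so this stays open for it. With the detection count of each array as a covariate the median difference of the 6 was 1.51 with an SE of 0.56, against 1.53 with an SE of 0.30 without it, which by the median alone would have spoken against a sensitivity trend, but miR-34a went from 1.56 ± 0.31 to 0.84 ± 0.53 and miR-127 from 2.06 ± 0.38 to 1.57 ± 0.73, while miR-379, near the detection limit, went from 1.19 ± 0.25 to 1.67 ± 0.45 and alone had a p under 0.05 adjusted over the 6. All 6 calls ended as the SE grew, the count correlating with group at r = 0.853. The difference also shrank for miR-34a, miR-127 and miR-685, the last from 2.02 to 1.70. It shrank less for miR-146b (1.51 to 1.44) and miR-362-5p (1.07 to 1.02). An array-wide sensitivity trend thus cannot be told apart from an effect on these miRNAs. Of the 15 splits of the arrays into 2 and 4, 1, the real one itself, gave 6 calls, the others gave at most 5, and 15 splits are too few for a share under 0.05; a biological effect of the transgene stays open and untested beyond this comparison of genotypes, and the labels name no other difference between the groups.

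hsa-miR-1826 and hsa-miR-923 carry names since ascribed to fragments of ribosomal RNA. miR-1826 had log2 values of 12.5 ± 0.12 in TG (SD, n = 2) and 9.14 ± 0.66 in WT (SD, n = 4). Brightness-dependent sensitivity is argued against for it, because the highest difference among 232 animal probe sets of similar WT brightness was 1.46. More fragmented RNA in the TG samples may be a candidate explanation, but of the other names ascribed to fragments of longer RNAs that were detected, 2 of 4 lay above all WT arrays (miR-1308 and miR-720) and 2 below (miR-805 and mml-miR-886-5p). That count would have spoken against fragmentation, but 3 names more than 1 log2 unit above the detection limit were required after it was seen, and only 2 of these 4 lie there; 15 such names were looked at in all, and no measure of RNA integrity was used here, so the explanation cannot be told apart from a change in the transgenic lung.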

How the results depend on the processing

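The alternatives with subsets of the WT arrays, without a block on 4 arrays, with averaged probe sets and with the detection count were chosen after seeing the data, and the others before. The count of 6 called miRNAs, all higher, was kept under centring on the plant median, robust eBayes and a fold change of at least 1.5, with 0 lower. The count was 9 with a variance trend, all higher, of which 5 were among the main calls and 4 were new, while miR-34a was lost. It was 1 without a filter, 2 at the 99th plant percentile, 1 with detection on 4 or more arrays, 0 with quantile normalization, 2 with centring on the tested median and 1 with all animals tested together, all higher. Array weights gave 33 (30 higher, 3 lower). Leaving out 1 array gave 0 to 27 calls, 0 to 24 higher and 0 to 3 lower, with 0 without TG replicate 1, TG replicate 2, WT replicate 1 or WT replicate 3, and with the lone TG array of 2 of these fits assumed to vary like WT. With only WT replicates 1 and 4 there were 31 (29 higher, 2 lower), or 36 (32 higher, 4 lower) with the filter of all 6 arrays. With only WT replicates 2 and 3 there were 6, of which 5 were among the main calls, but 0 of 197 with the filter of all 6 arrays, where the smallest adjusted p was 0.0837 and 30 had an unadjusted p under 0.05. With the variance prior of the 197 on the 187 probe sets of the smaller filter, 0 passed (smallest adjusted p 0.0795), and with the prior of the 187 for these and adjustment over 197, 1 did, so the filter acts on this count through the prior and the number tested. Averaging gave 14 (13 higher, 1 lower) and the detection count 0, with 10 at an unadjusted p under 0.05. With quantile normalization 33 had an unadjusted p under 0.05. The cause of the other shifts was not tested, apart from the fewer arrays or tests that some settings imply.

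The replicate block on the arrays numbered 1 and 2 gave 12 calls (9 higher, 3 lower, 5 of the main calls kept), 2 lists, 0 small nucleolar RNAs and a miR-21 difference of 0.91, against 0 calls and 1 list without the block on those arrays. Same-numbered arrays correlated at -0.21 and 0.07 in their deviations from group means. The deviations of the 2 TG arrays mirror each other, so these are not separate checks. They cannot tell whether same-numbered samples share more than a number.

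Called lists numbered 1 without a filter, with centring on the tested median and with the detection count, 4 at the 99th plant percentile, 0 with an estimated correlation, 2 with fry and 2 to 3 when leaving out 1 array. Robust eBayes gave no list value. Called small nucleolar RNAs numbered 6 with array weights, 5 with a trend, 1 at the 99th percentile, 1 with 4 or more arrays, 0 with quantile normalization, centring on the tested median or the detection count, 4 with only WT replicates 1 and 4 (5 with the filter of all 6 arrays), and 0 to 3 when leaving out 1 array. The miR-21 difference passed the threshold with array weights (1.05), only WT replicates 2 and 3 (1.20) and averaging (1.01), and ran from 0.81 to 1.22 when leaving out 1 array.

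Of 1099 values of the other 48 named miRNAs, 929 kept direction and side of the threshold, 71 lost the call, 37 gained one and 62 changed sign, none of these past the threshold. With centring on the tested median the sign changed for miR-122 (-0.088), miR-181b (-0.13), miR-181c (-0.10), miR-183 (-0.36), miR-24 (-0.17), miR-29c (-0.23), miR-34c (-0.27), miR-375 (-0.18), miR-467f (-0.26), miR-486 (-0.13) and miR-669c (-0.37), since that shifts every difference down. With the detection count it changed for let-7b (-1.14), let-7c (-0.78), miR-145 (-0.36), miR-15b (-0.46), miR-181b (-0.88), miR-183 (-0.76), miR-23b (-0.31), miR-24 (-0.48), miR-29a (0.43), miR-29c (-0.16), miR-30a (0.14), miR-342-5p (-0.095), miR-34c (-0.38), miR-375 (-0.81), miR-486 (-0.94) and miR-669c (-0.40). With the replicate block, and without it on the same arrays, it changed for miR-181b (-0.46), miR-183 (-0.090), miR-29a (0.31), miR-451 (0.26) and miR-486 (-0.00264). With only WT replicates 2 and 3, under both filters, it changed for miR-181b (-0.16), miR-183 (-0.10), miR-24 (-0.035), miR-29a (0.027), miR-486 (-0.39) and miR-669c (-0.063), and with only WT replicates 1 and 4 for miR-451 (0.063). It changed for miR-24 (-0.024) with quantile normalization and miR-29c (-0.050) with averaging. Leaving out 1 array, the range crossed 0 for miR-34c (-0.083 to 0.33), miR-486 (-0.16 to 0.56), miR-181b (-0.22 to 0.60), miR-183 (-0.000583 to 0.34), miR-669c (-0.00361 to 0.25), miR-451 (-0.13 to 0.15) and miR-29a (-0.39 to 0.060). For 10 more it kept its sign and moved by over 1.5 times: miR-31 (0.63 to 1.15), miR-375 (0.00587 to 0.50), let-7a (-0.19 to -0.070), miR-342-5p (0.15 to 1.07), miR-143 (-0.69 to -0.25), miR-199b (-0.78 to -0.34), miR-106b (-0.98 to -0.22), miR-15b (0.36 to 0.81), miR-24 (0.15 to 0.42) and miR-122 (0.30 to 0.53). The filter was recomputed in each of these fits. miR-379, miR-449a, miR-205 and miR-467f were thus tested in 4 of the 6, all with both TG arrays. miR-223, miR-133b, miR-183, miR-669c and miR-122 were also tested in only 4. The ranges of these miRNAs do not cover every array left out. None of the 6 called miRNAs moved so far in the fits that tested it, or under averaging, but miR-379 had no fit without a TG array. Averaging moved 16 others by over 1.5 times, to 0.44 for miR-146a, 0.21 for miR-155, -0.00239 for miR-223, 0.34 for miR-34c, -0.31 for miR-451, 0.37 for miR-342-5p, -0.00322 for miR-133b, 0.80 for miR-199a-5p, -0.21 for miR-199b, -0.045 for miR-106b, 0.22 for miR-15b, 0.13 for miR-181c, 0.21 for miR-183, -0.71 for miR-10a and 0.083 for miR-122, beside miR-29c. Of 42 named miRNAs with a detected probe set of another mammal, 34 had all of these of 1 sign with the mouse one; the others were miR-223, miR-133b, miR-106b, miR-15b, miR-29a (12 of 13), miR-181c (7 of 8), miR-182 (4 of 5) and miR-23b (8 of 9). Averages take in undetected probe sets, and for miR-155 and miR-199b 0 probe sets of other mammals were detected. Both of these averages mix the mouse value with background. The cause of the other changes was not tested. Probe sets near the detection limit, among them miR-183, miR-669c, miR-467f, miR-29c and miR-122, have little signal over background to carry a direction.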

Other observations

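Every test in this part was chosen only after the result was seen.

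The miRNA genes next to Mir362 in the RefSeq table (Mir500, Mir501, Mir188 and Mir532, within 50 kb) were not among the fixed lists. Of 5 tested probe sets of this neighbourhood all had positive differences and 4 had both TG arrays above all WT arrays. miR-500 differed by 1.38 ± 0.42 (SE), miR-532-5p by 1.18 ± 0.41, miR-501-3p by 0.77 ± 0.27 and miR-532-3p by 0.27 ± 0.29, beside the called miR-362-5p. The mean was 0.93. A joint rise of this neighbourhood is a hypothesis that stays open: camera gave p = 0.181 with an estimated correlation of 0.50 and p = 0.00694 with the preset one, unadjusted, and the neighbourhood was picked because a member had been called.

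Averaging the same-name probe sets of all mammals gave 14 calls, 13 higher and 1 lower, with all 6 main calls among them. The one lower was miR-195, at a difference of -0.85 ± 0.16 (SE) and an adjusted p of 0.0379 by limma, with all 7 other-mammal probe sets of its name below 0. miR-21 was among the 14 at 1.01 ± 0.17 with an adjusted p of 0.0225. The averages take in every mammal's probe set of a name, whether or not it binds the mouse RNA, and leave the number of animals as it was.

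let-7b and let-7c were lower on WT replicates 1 and 4 than on WT replicates 2 and 3, by log2 differences of -1.77 and -1.24. A loss of the whole let-7 family is argued against, since the median difference of the other 6 tested members was -0.12, although let-7d differed by -1.04. The standard error of the mean of these 6, not of their median, was 0.19. A sharp ceiling of the signal on these arrays predicts no fall below it. Yet 13 tested miRNAs with log2 values of 9 to 11 had a median difference of -0.29 with quartiles of -0.66 and -0.21. let-7d went from 11.21 to 10.17. These values lean against a sharp ceiling without excluding it. The median over all tested probe sets was itself -0.20. The median of the 13 also lies within its interquartile half-width of 0.22 from -0.15, the fall allowed under a ceiling. A loss that grows gradually with brightness was not tested and stays open. let-7e at 9.92 and let-7a at 10.18 differed by -0.53 and -0.21, and the dimmer let-7i, let-7f and let-7g by -0.03, 0.11 and 0.18. miR-24 at 11.38 differed by -0.61, but miR-126-3p at 10.08 by 0.58. No biological explanation was tested, as the design gives none within WT.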
